A study of Mus musculus with 6 samples.

How the data were processed

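Retinal RNA was measured on one-colour Affymetrix arrays with biotin-labelled cRNA, per the labels' protocols, in 3 wild-type and 3 knockout-labelled samples. The deposited values are on a log2 scale and were made with RMA, per the submitters' processing notes, which corrects background, normalizes between arrays and summarises probes per probe set. The software, version and chip definition behind RMA are not given in the sources used here. RMA brings all arrays to nearly the same distribution (medians 5.77 to 5.80), so a change in total RNA cannot be seen, and the values carry no detection calls. The deposited log2 values were used without further scaling. All 6 value columns were used.

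Of 45101 probe sets, 64 are controls and were left out, leaving 45037. The platform annotation gives 34945 of these 1 gene, 932 several and 9160 none. A probe set with several genes was never named. Each gene was represented by the probe set with the highest mean over all 6 arrays, which gave 18193 genes. Of these, 18032 matched the RefSeq table of assembly GRCm38.p6 by Entrez identifier. That table was used only for names, chromosomes and gene order, since the build behind the array annotation is not given in the sources used here and no coordinates are printed.

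Knockout was compared with wild type by limma 3.58.1 (lmFit and eBayes without trend or robust options) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, of which 441 of 488 names were measured. Lists with fewer than 5 measured members get no test. Each list was also tested with an estimated correlation and with fry. Neighbours of Nxnl2 were the 50 nearest measured genes on each side. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes every Nxnl2 probe set, up to 15 called genes per direction whose groups do not overlap, filled to 10 with the smallest unadjusted p, and up to 4 members of each list with the smallest p. From these the text gives a selection, and the genes given for single arrays were chosen after their values were seen. Lists of other tissues were written after the leading genes of the array labelled knockout replicate 3 had been seen.

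The 6-array comparison is the prescribed one. The comparison of 5 arrays leaves out the array labelled knockout replicate 3 and was planned as one of the alternatives. The alternatives were a variance trend with robust fit, array quality weights, quantile normalization applied again, centring on the median or the 75th percentile, removal of probe sets below the 40th percentile, the replicate number as a block, each array left out, other rules for several probe sets of a gene, a threshold of 0.1, a 1.5-fold minimum, and no X or Y genes. A further alternative for linear values did not apply.

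The procedure was tested on simulated data with the wild-type means of 18193 genes and spreads drawn from limma's fitted prior. For 3 against 3 simulated retina arrays, 68.7% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 9 false calls. For 3 against 2, the shares were 53.7%, 95.5% and 100%, with 10 false calls. With 1 simulated array replaced by the measured array labelled knockout replicate 3, 0% was recovered at each fold. For both sizes of comparison, camera called 14 of 14 simulated lists of 20 genes shifted by 0.25 and 0 of 15 unchanged lists, with either correlation. Simulated genes are independent, so this does not cover genes that move together in a real list.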

Results

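Gene expression was measured in retinas of BALB/c AJ mice at post-natal day 40, dissected away from the pigment epithelium. Nxnl2, the gene deleted in the knockout, encodes a thioredoxin-like protein made in photoreceptors and known as rod-derived cone viability factor 2. Wild-type retina was hybridised to 3 arrays and 3 more arrays carry the label of the homozygous knockout. Each array gave a log2 value for 45037 probe sets other than controls, of which 34945 named exactly 1 gene, and these covered 18193 genes. The comparison asks which retinal transcripts differ when Nxnl2 is missing. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

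Nxnl2 itself was near background in 2 of the 3 arrays labelled knockout and clearly present in the other. The brighter Nxnl2 probe set read 11.42 ± 0.04 (log2, SD, n = 3) in wild type, 3.78 in knockout replicate 1 and 3.73 in knockout replicate 2. The array labelled knockout replicate 3 read 9.21. The dimmer probe set read 8.51 ± 0.26 (SD, n = 3) in wild type, then 4.25, 4.11 and 6.83 in the same order. Values of knockout replicates 1 and 2 lie below the brightest Bacillus control probe sets of their arrays (4.29 and 4.41), which match no mouse transcript, so the Nxnl2 signal left there cannot be told from background. Nxnl2 thus goes against the label of 1 array, which is called the array labelled knockout replicate 3 throughout.

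**Figure D1:**
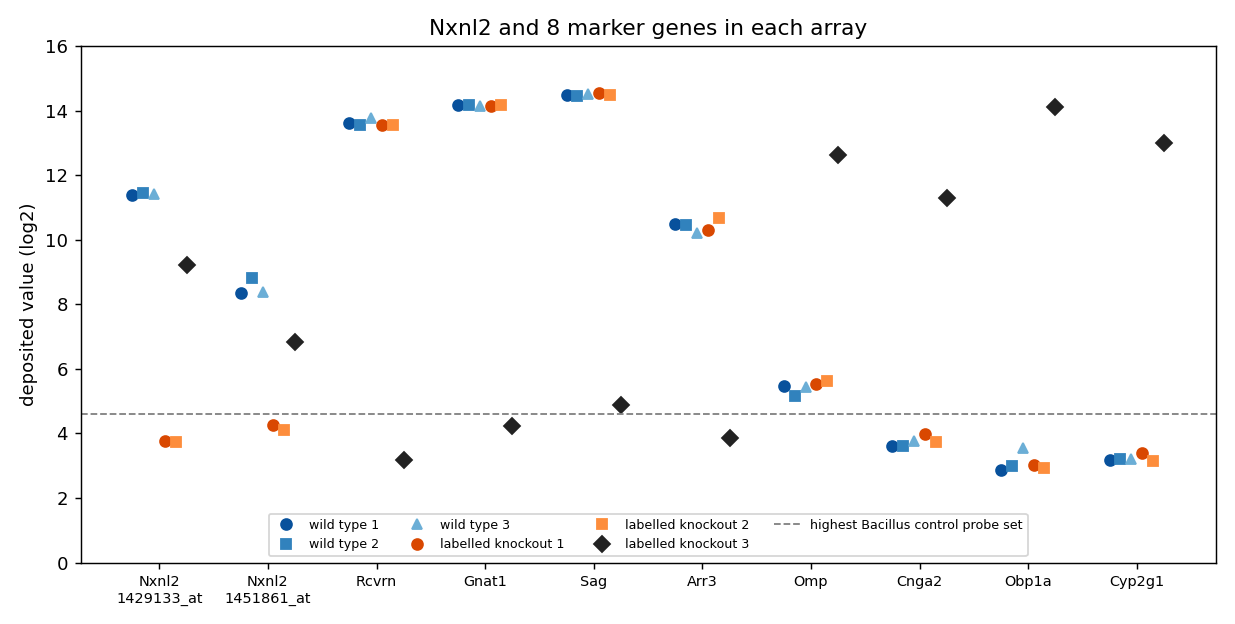
Deposited log2 values of both Nxnl2 probe sets and of 8 marker genes, 1 point per array, with the highest Bacillus control probe set as a dashed line. The array labelled knockout replicate 3 reads 9.21 for the brighter Nxnl2 probe set, reads 3.18 to 4.89 for the photoreceptor genes Rcvrn, Gnat1 and Sag, and reads 14.1 for Obp1a, where the other 5 arrays average 3.07.

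In the array labelled knockout replicate 3 most photoreceptor transcripts lay far below the other arrays, and odorant-binding and olfactory transcripts were abundant. Recoverin (Rcvrn), the calcium sensor of photoreceptors, read 3.18 there against 13.61 ± 0.10 (SD, n = 5) in the other arrays. Rod transducin (Gnat1) read 4.23 against 14.16 ± 0.01 (SD, n = 5), and rod arrestin (Sag) read 4.89 against 14.49 ± 0.03 (SD, n = 5). Of the 26 measured rod markers, 25 lay more than 2 log2 units below the other 5 arrays, as did 11 of the 15 cone markers. In the other direction, the odorant-binding protein gene Obp1a read 14.12 against 3.07 ± 0.26 (SD, n = 5). Bpifa1, a secreted protein of airway epithelium, read 14.12 against 3.27 ± 0.17 (SD, n = 5). Cyp2g1, a cytochrome P450 of olfactory mucosa, read 12.99 against 3.22 ± 0.10 (SD, n = 5). Over all genes, 1354 lay more than 2 log2 units above the other 5 arrays and 817 lay as far below. Each of those 5 arrays, set against the rest of the 5, had at most 14 genes as far above and at most 2 as far below. Its correlation with each other array over probe sets was 0.848 to 0.853, against 0.994 to 0.996 for the 10 pairs among the other 5 arrays, and no 2 arrays held identical values.

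**Figure D2:**
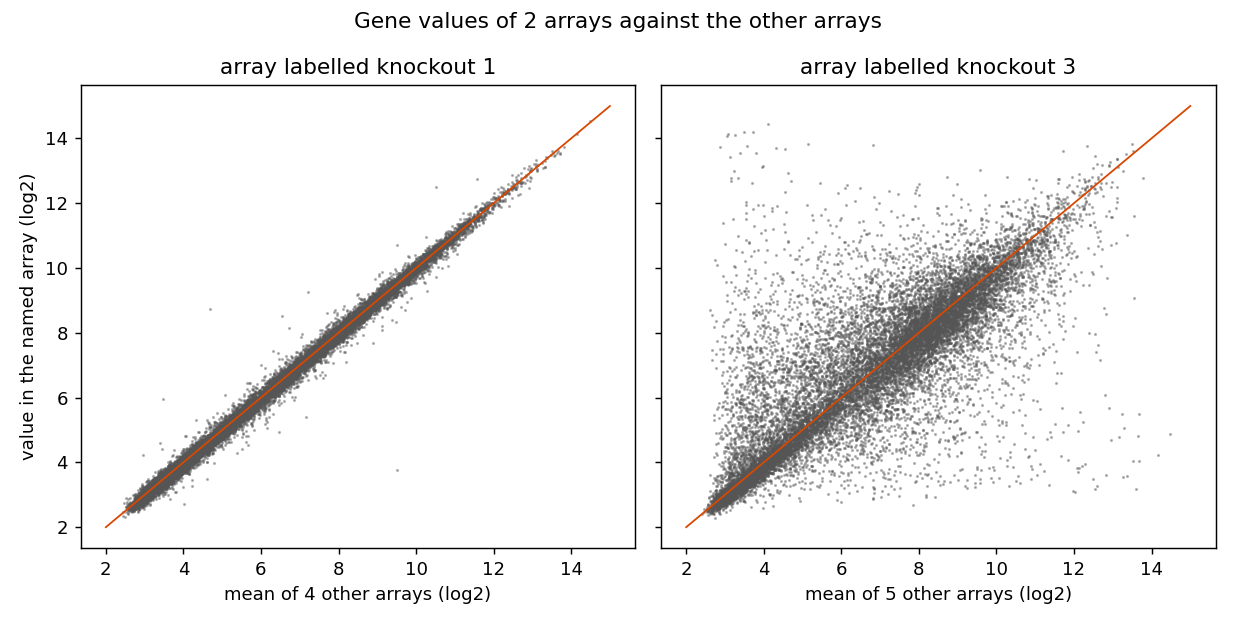
Gene values (log2) of the array labelled knockout replicate 1 (left) and of the array labelled knockout replicate 3 (right) against the mean of the other arrays, leaving the latter out of both means, with 1 point per gene and the line of equal values. The left points follow the line, while 1354 genes of the right array lie over 2 log2 units above the other 5 arrays and 817 lie as far below.

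With all 6 arrays, as the design prescribes, no gene was called. The largest mean difference among the named genes was that of Nxnl2, with a log2 change of -5.85 (SE 1.56, limma adjusted p = 0.745). By limma, 0 of 18193 genes and 0 of 45037 probe sets passed an adjusted p of 0.05, and 132 genes had an unadjusted p under 0.05 where chance gives 910. Genes with the smallest p included the lymphocyte receptor gene Cd22 (0.45, SE 0.13) and the endothelial phosphatase gene Ptprb (0.56, SE 0.15) on the higher side. On the lower side stood Glo1, the glyoxalase of methylglyoxal removal (-0.89, SE 0.25), and Arrdc2 (-0.69, SE 0.13). None of these passed, all with an adjusted p = 0.745. The knockout and wild-type values did not overlap for 8.64% of genes, where chance gives 10%. With array quality weights 2 genes passed, Nxnl2 and Erdr1.

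Among the 29 gene lists, 19 passed in the 6-array comparison by camera with its preset correlation, 8 higher and 11 lower. Rod markers had a median log2 change of -2.79 and cone markers one of -1.97, while complement genes stood at 0.78 and microglia markers at 0.71. No list held with an estimated correlation: the adjusted p was 0.440 for each of these 4 lists. In the array labelled knockout replicate 3 alone the rod list lay -8.32 from the wild-type mean and the complement list 1.62. Müller glia markers, which did not pass (adjusted p = 0.398), had a median of 0.08 against a mean of -0.18. Adjusted over the list alone 0 genes passed in any list. Without that array 2 genes were called and 8 lists passed, none of which held with an estimated correlation (adjusted p = 0.660) or by fry.

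Without the array labelled knockout replicate 3, a setting planned in advance and chosen to lead the account after its values were seen, 3 wild-type and 2 knockout arrays remain. In these, the Nxnl2 transcript fell to background, Erdr1 rose, and no other gene passed. The brighter Nxnl2 probe set fell by 7.67 on the log2 scale (SE 0.09, limma adjusted p = 1.1e-09 over genes). The dimmer one fell by 4.33 (SE 0.15, adjusted p = 2.96e-05 over probe sets). Erdr1, named for a role in erythroid differentiation, rose from 11.24 ± 0.07 (SD, n = 3) to 12.66 ± 0.13 (SD, n = 2), a log2 change of 1.42 (SE 0.10, adjusted p = 0.00283). Its dimmer probe set changed by 0.45 and did not pass. With the mean of both Erdr1 probe sets the change was 0.94 (adjusted p = 0.0928), and without wild-type replicate 3 it was 1.39 (0.0528). The Erdr1 probe set is of the kind that can also bind transcripts of other genes. The reference places Erdr1 on a sex chromosome, and sex-linked transcripts were uneven among the arrays. At an unadjusted p under 0.05 stood 628 genes, where chance gives 910, and 16.5% of genes had groups that did not overlap, where chance gives 20%. Leaving out knockout replicate 1 as well gave 8 genes, among them the muscle genes Myh4 and Tnnt3, and leaving out knockout replicate 2 as well gave 8, among them Edn2 and Fgf2; both sets hold Nxnl2 and Erdr1.

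Over probe sets, 5 passed in the 5 arrays, 1 higher and 4 lower. Beside those of Nxnl2 and Erdr1, these were 2 probe sets without a gene name in the annotation used here, with log2 changes of -6.38 (SE 0.12, adjusted p = 2.15e-07) and -4.45 (SE 0.20, adjusted p = 1.61e-04). They read 3.35 and 4.20 in knockout replicate 1, and 3.63 and 3.52 in knockout replicate 2. In the array labelled knockout replicate 3 they read 5.75 and 4.08, against wild-type values of at least 9.82 and 8.14. The first thus lay above both other knockout arrays there, and the second lay between them.

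The next genes by p did not pass in this comparison. On the higher side, 1600012H06Rik stood at 0.79 (SE 0.10, adjusted p = 0.190), with its other probe set at 0.78, and passed only with a variance trend and robust fit (adjusted p = 0.0248). Samd4, an RNA-binding repressor of translation, stood at 0.73 (SE 0.11, adjusted p = 0.342), with its other probe sets at 0.62, 0.37 and -0.02 (mean levels 5.55, 3.96 and 3.12). Ahrr, the repressor of the aryl hydrocarbon receptor, stood at 0.76 (SE 0.13), and Wwtr1, the Hippo pathway co-activator TAZ, at 0.56 (SE 0.10), with its other probe sets at 0.29 and 0.22. Sox30 stood at 0.93 and passed without knockout replicate 2 (adjusted p = 0.0317). Values for G530011O06Rik (1.11), Arfgef1 (0.81), Cspp1 (0.79) and Hcfc2 (0.57) complete that side. On the lower side stood Exoc3l4 (-1.13), Sostdc1 (-0.94, other probe set -0.74), 6330415G19Rik (-0.79), Myo5c (-0.74), Arrdc2 (-0.62), Bmp2 (-0.58) and Shisa2 (-0.41). Other probe sets of Arfgef1 (-0.76), 6330415G19Rik (0.14), Myo5c (0.07) and Shisa2 (0.02) had the opposite sign, and those of Cspp1 and Hcfc2 lay between -0.16 and 0.06.

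Rod markers shifted lower as a list in the 5 arrays, by a median log2 change of only -0.03 over 26 members (camera adjusted p = 0.0117), and cone markers did not shift. The rod call was lost with an estimated correlation (adjusted p = 0.660). Adjusted over all genes no rod gene passed, and adjusted over the list alone 2 fell. One was Prph2, the peripherin of outer segment discs, at -0.77 (SE 0.13, adjusted p = 0.00599 over the list alone, 0.578 over all genes). The other was Esrrb, an orphan nuclear receptor of rods, at -0.51 (SE 0.09, adjusted p = 0.00599 over the list alone, 0.681 over all genes), whose other probe sets gave -0.34 and -0.04. Without knockout replicate 1 the rod median was 0.02 (adjusted p = 0.534), and without wild-type replicate 3 it was -0.01 (0.125). The rod call was lost in 6 of 19 alternatives. Of the 15 cone markers, 9 lay above 0 and the median was 0.04 (camera adjusted p = 0.654). Cone opsin Opn1mw stood at 0.11 (SE 0.12), the cone transducin subunit Gnb3 at 0.19 (SE 0.16) and cone phosphodiesterase Pde6c at -0.10 (SE 0.12). Visual cycle genes had a median of -0.08 (adjusted p = 0.103) and ribbon synapse genes one of -0.04 (adjusted p = 0.197).

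Genes of injured retina, microglia and complement shifted higher as lists in the 5 arrays. The reactive glia and retinal injury list had a median log2 change of 0.25, with 23 of 24 members above 0 (camera adjusted p = 1.07e-07). Microglia markers stood at 0.17 with 17 of 19 above 0 (6.7e-06), complement genes at 0.20 with 12 of 12 above 0 (5.51e-06), and Müller glia markers at 0.09 with 12 of 18 above 0 (0.0385). The adjusted p = 0.660 with an estimated correlation for each of these 4 lists. Adjusted over all genes none of their members passed. Adjusted over the list alone, C1qb, a chain of the first complement component, rose by 0.50 (SE 0.11, adjusted p = 0.0220 over complement and 0.0348 over microglia). The microglia and complement lists share C1qb, C1qa and C1qc, so their shifts are not independent.

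Knockout replicate 1 carried most of the glial difference. The reactive glia list lay 0.36 above the wild-type mean in knockout replicate 1 and 0.09 above it in knockout replicate 2, with wild-type arrays between -0.08 and 0.08. Complement genes lay 0.17 and 0.19 above the wild-type mean in knockout replicates 1 and 2, where the muscle list lay at -0.39 and 2.04. Edn2, the endothelin released by stressed photoreceptors, read 8.73 in knockout replicate 1, 5.06 in knockout replicate 2 and 4.55 ± 0.35 (SD, n = 3) in wild type. Fgf2, a survival factor of injured retina, read 4.23, 3.05 and 2.94 ± 0.10 (SD, n = 3) in the same order. These Fgf2 values lay below the highest Bacillus control of their arrays (4.29 in knockout replicate 1), so they cannot be told from background. The acute-phase ferroxidase gene Cp read 9.74, 9.10 and 9.03 ± 0.02 (SD, n = 3). Timp1, the member of the reactive glia list with the smallest p, was instead higher in knockout replicate 2, at 4.69, 4.87 and 4.38 ± 0.21 (SD, n = 3). Without knockout replicate 1 the median shifts were 0.09 for reactive glia (adjusted p = 0.408), 0.06 for microglia (0.919), 0.03 for Müller glia (0.919) and 0.19 for complement (0.00661). The Müller glia call was lost in 10 of 19 alternatives, among them those without wild-type replicate 1 (0.0941) or 3 (0.125).

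**Figure D3:**
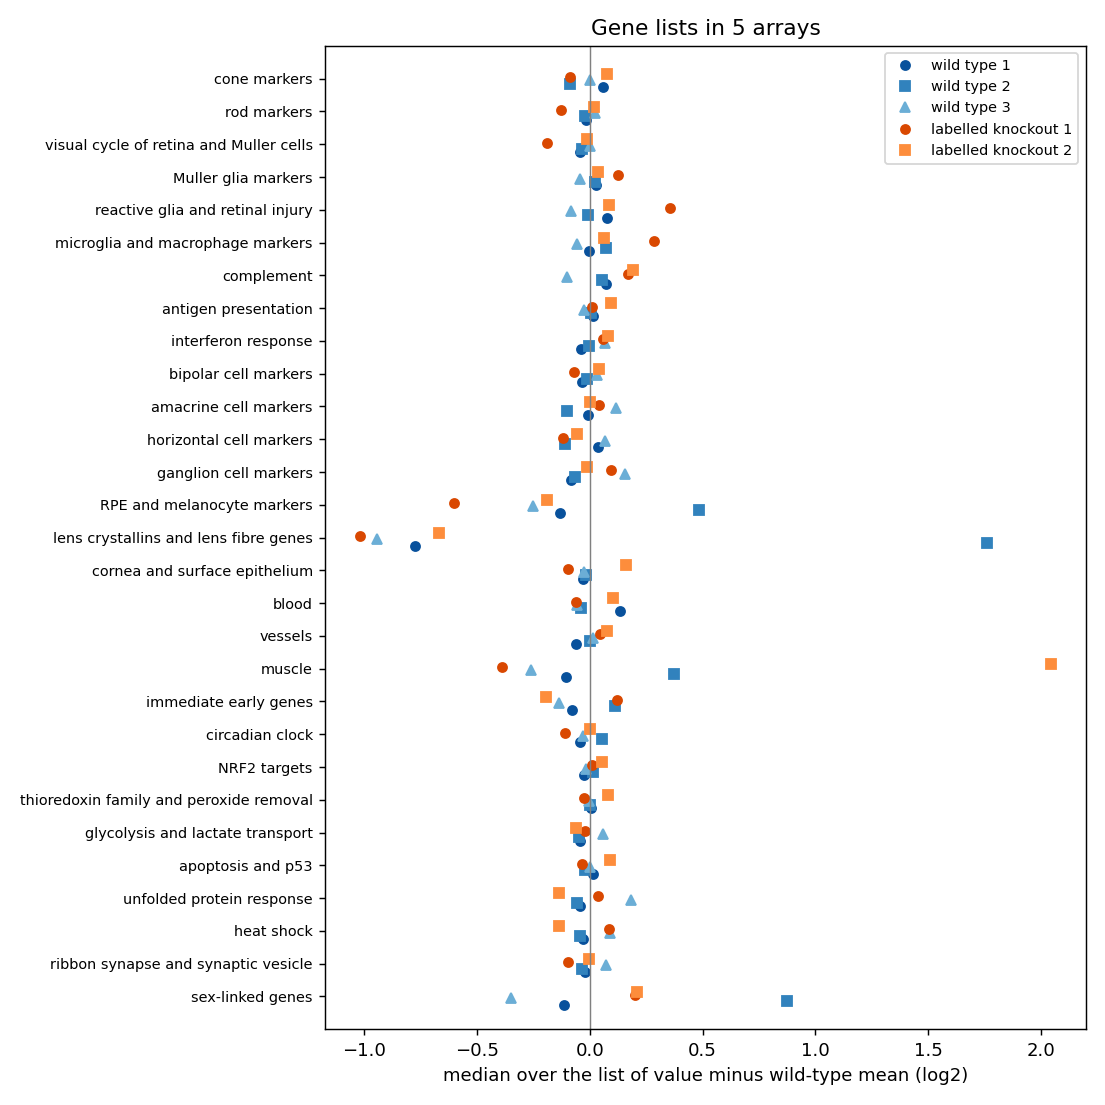
Median over each gene list of the log2 value minus the wild-type mean, 1 point per array, for the 5 arrays without the one labelled knockout replicate 3. The muscle list stands at 2.04 in knockout replicate 2 alone, the lens list at 1.76 in wild-type replicate 2 alone, and the reactive glia list at 0.36 in knockout replicate 1.

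Lens, pigment epithelium and muscle lists differed between single arrays. Lens genes had a median log2 change of -0.80 (camera adjusted p = 5.51e-06) and pigment epithelium genes one of -0.41 (1.41e-05), while muscle genes stood at 0.90 (6.69e-04). For each of these 3 lists the adjusted p = 0.660 with an estimated correlation. The lens list lay at 1.76 in wild-type replicate 2 and between -1.02 and -0.67 in the other 4 arrays. Without wild-type replicate 2 its median change was 0.01 (adjusted p = 0.948), and that of the pigment epithelium list was -0.15 (0.00835). Without knockout replicate 1 the pigment epithelium list stood at -0.19 (0.378). Beaded filament gene Bfsp2 stood at -0.39 (SE 0.21), crystallin gene Cryba4 at -1.23 (SE 0.82) and tyrosinase gene Tyr at -0.79 (SE 0.27). The muscle list lay at 2.04 in knockout replicate 2 and -0.39 in knockout replicate 1, and without knockout replicate 2 its median was -0.39 (adjusted p = 0.00264). With dim probe sets removed the muscle call was lost (0.0810). The muscle myosin gene Myh4 read 5.92 in knockout replicate 2, against 3.08 or less in the other 4 arrays.

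No other list passed in the 5 arrays. Among redox genes, of interest since Nxnl2 belongs to the thioredoxin family, the median was 0.03 for thioredoxin and peroxide removal (camera adjusted p = 0.654) and 0.04 for NRF2 targets (0.557). Glycolysis and lactate transport stood at -0.05 (0.155), where the lactate exporter gene Slc16a3 was at -0.50 (SE 0.22) and hexokinase gene Hk2 at -0.39 (SE 0.17). Medians were 0.01 for bipolar cells (0.838), 0.02 for amacrine cells (0.654), -0.09 for horizontal cells (0.294) and 0.06 for ganglion cells (0.294). Stress lists stood at -0.02 for apoptosis and p53 (0.924), -0.05 for the unfolded protein response (0.230), 0.00 for heat shock (0.654) and -0.07 for immediate early genes (0.654). The median was 0.06 for antigen presentation (0.384), 0.07 for interferon response (0.0888), 0.10 for vessels (0.0861), 0.06 for blood (0.320), 0.06 for surface epithelium (0.230) and -0.05 for clock genes (0.230). The interferon list passed in 5 of 19 alternatives, with the smallest adjusted p of 0.00959 for the most variable probe set. The unfolded protein response passed in 2. Amacrine, clock, surface epithelium, glycolysis, vessel, visual cycle and sex-linked lists passed in 1 each. Heat shock and immediate early genes each passed in 1 with the direction kept and in 1 with it reversed. Ganglion cell markers passed in 3 of 19, among them those without wild-type replicate 3 (6.78e-04) or knockout replicate 2 (0.0427). For bipolar cells and heat shock the mean and the camera direction were negative against a positive median.

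Sex-linked transcripts were uneven among the arrays. One probe set of Xist, the RNA of the inactive X chromosome, read 6.39 in wild-type replicate 2 and 9.10 to 10.93 in the other 5 arrays. The brighter probe set of the Y-linked gene Eif2s3y read 9.05 in wild-type replicate 2, and 7.72 and 7.73 in wild-type replicates 1 and 3. It read 8.51 and 8.61 in knockout replicates 1 and 2, and 7.42 in the array labelled knockout replicate 3. Both of these probe sets lay above the highest Bacillus control of every array (4.13 to 4.60). In wild-type replicate 2 a dimmer Xist probe set read 3.93, below the highest control there (4.60), and the brightest read 7.83. Each sample may thus mix RNA of both sexes, though for wild-type replicate 2 not every Xist probe set shows this. How many animals a sample holds was not tested. As a list, sex-linked genes had a median of 0.15 in the 5 arrays (camera adjusted p = 0.230). The list joins Xist with Y-linked genes, which differ in opposite directions between the sexes. Its test therefore cannot show whether the groups differ in sex. Of the 100 genes nearest to Nxnl2 in the reference gene order, 50 on each side, 0 passed in either comparison by limma. At an unadjusted p under 0.05 stood 2% of them in the 5 arrays, against 3.45% of other genes (Fisher's exact test, two-sided, p = 0.588), and 0% against 0.724% in the 6 arrays.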

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

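Alternatives on the 5 arrays were chosen after seeing the data. With 6 arrays, the counts of called genes and probe sets moved from 0 only with array quality weights (2 genes, 1 higher and 1 lower, and 5 probe sets) or without the array labelled knockout replicate 3 (the same counts), and a threshold of 0.1 gave 1 probe set. Leaving out each array gave 0 to 2 genes, 0 to 1 higher, 0 to 1 lower, 0 to 5 probe sets and 8 to 22 lists. Nxnl2 passed with array quality weights (-7.61) and ranged from -7.67 to -4.92 with an array left out. The 19 lists became 6 with array quality weights and 0 with an estimated correlation, fry directional or fry mixed. With 5 arrays, trend and robust options gave 2 higher genes, and the mean of all probe sets left 1 gene and 0 higher. Without X and Y genes the counts of genes were also 1 and 0 higher, but Erdr1 is not tested in that setting. Leaving out each of the 5 arrays gave 1 to 8 genes, 0 to 7 higher, 1 to 2 lower, 4 to 11 probe sets, 7 to 14 lists and Nxnl2 at -7.69 to -7.64; with 1 knockout array left it is assumed to vary like the wild type. The 8 lists became 0 with an estimated correlation, fry directional or fry mixed. Neighbour counts stayed at 0 with 25 or 100 genes on each side.

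The labels do not say that a replicate number marks a shared animal, litter or day, so the numbers are not read as pairs. Correlations of same-numbered arrays (-0.07, -0.01 and -0.08 in 6 arrays, -0.07 and 0.08 in 5) decide nothing: the array labelled knockout replicate 3 sets the knockout mean in the former, and centring 2 arrays makes their values mirror images in the latter. With the replicate block 0 genes and 21 lists passed in 6 arrays (Nxnl2 -5.85), and 3 genes, 2 of them lower (Nxnl2 and Exoc3l4, adjusted p = 0.0479), 6 probe sets and 9 lists in 5 arrays (Nxnl2 -7.66).

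With single arrays of the 6 left out, cone markers ranged from -3.01 to 0.045 and amacrine markers from -0.91 to 0.021, both highest without the array labelled knockout replicate 3, and muscle from -0.33 without knockout replicate 2 to 0.90. With single arrays of the 5 left out, lens genes ranged from -1.31 to 0.0073 without wild-type replicate 2. Without knockout replicate 2, muscle was at -0.39 (range to 2.04), immediate early genes at 0.12 (range from -0.19) and heat shock at 0.085 (range from -0.14). The cause was not tested. Medians also changed sign with no array left out: in 6 arrays with array quality weights, cone markers stood at 0.042 and amacrine markers at 0.015. These values lie near those without the array labelled knockout replicate 3 (0.045 and 0.021), so they show no separate source of change. Lists near 0 also changed sign, in both comparisons. In 5 arrays the Müller glia call was also lost with array quality weights (0.0554), the most variable probe set (0.0776) and the probe set brightest over the 5 arrays (0.0934). With the replicate block the Müller glia (0.0982) and rod (0.134) calls were lost. Genes near the level of the Bacillus controls give only bounds on a change.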

Other observations

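Among the tests below, those for failed hybridisation, for a mixture, for the olfactory tissue, for Nxnl2 in that array, for other tissue at dissection, for sex in the microglia and complement lists, for the complement list without each knockout array, and for the lens and pigment epithelium were chosen only after the result was seen, as were each further array left out of the 5 and the splits of single lists, and the comparison of 5 arrays was chosen to lead after its values were seen.

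The array labelled knockout replicate 3 also held olfactory neuron, gland and ciliated cell transcripts. The olfactory marker protein gene Omp read 12.61 against 5.44 ± 0.17 (SD, n = 5) in the other arrays, the olfactory channel subunit gene Cnga2 11.30 against 3.75 ± 0.15 (SD, n = 5), and the olfactory cyclase gene Adcy3 11.83 against 6.89 ± 0.14 (SD, n = 5). The mucin gene Muc5b read 11.93 against 5.13 ± 0.22 (SD, n = 5). Median differences were 5.78 for olfactory supporting cells and glands (11 genes) and 2.44 for motile cilia (14 genes). They were 1.0 for salivary gland, 0.46 for cornea and skin, 0.11 for kidney, 0.04 for lung alveoli, 0.02 for liver, -0.13 for testis, -0.69 for skeletal muscle and -0.85 for brain.

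Values assigned to the wrong probe sets would part the probe sets of a gene, yet the deviations of the 2 brightest probe sets correlated across genes with r = 0.758 (genes are not independent replicates), and hybridisation controls differed from the other arrays by a median of 0.0890 log2, within the 0.0462 to 0.0916 seen among those, which argues against failed hybridisation. These controls are added before hybridisation and do not test RNA quality. There, the Gapdh signal near the 3' end less that near the 5' end was 0.44 against -0.04 to 0.05 in the other arrays. The same measure for Actb was 1.07, within the 1.01 to 1.24 of the other arrays, so the 2 measures of RNA quality differ. An effect of the genotype would appear in the other knockout arrays, but the slope of their differences on those of this array was 0.00832 over 2177 genes. A mixture holding much retina RNA would keep rod transcripts, whose median was 4.04 against 4.13 for the highest Bacillus control and 12.86 in the other arrays. A small share of retina RNA stays open, since a median near background cannot exclude it and some rod genes, such as Sag (4.89), lay above that control. A candidate explanation is RNA of olfactory mucosa: the olfactory neuron list (15 genes, 3 of them also in retinal lists) lay 4.40 above the other arrays, against at most 3.31 for a list of any other tissue tested, the surface epithelium. Both Nxnl2 probe sets, at 9.21 and 6.83, lay at least 2.65 above the other knockout arrays, which argues against RNA of the same knockout. Of the 2 unnamed probe sets that fell in those arrays, 1 lay above them here (5.75) and 1 lay within their values (4.08 against 3.52 and 4.20). Which sample or step the RNA came from was not tested.

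The higher glia, microglia and complement lists may rest largely on 1 knockout array. Without knockout replicate 1 the reactive glia shift was 0.0875 (adjusted p = 0.408) and without replicate 2 the adjusted p was 6.35e-17, whereas the complement list stood at 0.191 (0.00661) without replicate 1 and passed without replicate 2 as well (5.99e-05), although with both it had an adjusted p = 0.660 with an estimated correlation. For sex composition, wild-type replicate 2, lowest in Xist, was compared with the other wild-type arrays. In the reactive glia list it differed by -0.00496 against a shift of 0.251, with an SD of 0.114 in the other wild-type arrays. In the microglia list it differed by 0.103 against 0.170. In the complement list it differed by 0.0699 against 0.203, with an SD of 0.120 in the other wild-type arrays. The reactive glia list thus showed no difference in that array, but a single array cannot decide against such a spread. Sex stays open for each of these lists. Against muscle, surface epithelium or blood carried along at dissection, these lists lay at -0.390, -0.0969 and -0.0615 in knockout replicate 1, each below the highest wild-type array, by -0.0795 at the nearest, but for the complement list in knockout replicate 2 this stays open, since muscle (2.04) and surface epithelium (0.163) lay above all wild-type arrays there, by up to 1.67. Vessel tissue cannot be told apart from an effect of the missing Nxnl2, and both stay open, since the vessel list of knockout replicate 1 lay at 0.0454 against 0.0140 in the highest wild-type array, an excess smaller than the wild-type range of 0.0753.

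For the lower lens and pigment epithelium lists, a candidate explanation is the amount of these tissues left at dissection. The lens list ranged over 2.70 log2 among the 3 wild-type arrays, more than the -0.799 between groups, and the pigment epithelium list over 0.735. Against an effect of the genotype on the lens list, its shift was 0.00734 (adjusted p = 0.948) without wild-type replicate 2, and the remaining wild-type arrays (-0.77 and -0.94) lay between the knockout arrays (-1.02 and -0.67). For the pigment epithelium list, at -0.15 (0.00835) without that array and -0.19 (0.378) without knockout replicate 1, the genotype stays open.

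Other splits of the arrays are too few for a share under 0.05. With 6 arrays the real split gave 0 genes and the highest other split 0, so 10 of 10 splits gave as many, and for lists the real split gave 19 and the highest other 22, with 4 of 10 giving as many. With 5 arrays the real split gave 2 genes and the highest other 0, so 1 of 10 gave as many, and for lists the real split gave 8 and the highest other 11, with 7 of 10 giving as many. Each of the 8 lists also passed in some of the 9 other splits of the 5 arrays: Müller glia in 2, rods and complement in 3, pigment epithelium in 5, reactive glia and muscle in 6, microglia in 7 and lens in 9. Another split gave a smaller adjusted p for Müller glia (0.00953), microglia (3.62e-09), pigment epithelium (2.07e-11), muscle (1.35e-14) and lens (2.41e-16), but not for rods, reactive glia or complement. Another split also gave a larger median, regardless of sign, for each list except reactive glia (0.246 against 0.251), such as 0.0992 against 0.0348 for rods, 0.188 against 0.170 for microglia and 0.213 against 0.203 for complement.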
